A study of Cellvibrio japonicus with 6 samples.

How the data were processed

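RNA from wild-type Cellvibrio japonicus grown on xylan was sequenced in 6 samples, 3 in exponential and 3 in stationary phase. Metabolism was stopped with an ethanol and phenol mixture, and total RNA was extracted and prepared for Illumina sequencing, per the labels' protocols. The aligner, the counting tool, their versions, ribosomal RNA removal and strand handling are not given in the sources used here.

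Both tables were deposited for the series and not for single samples, and the second holds the exponential comparison alone. The first holds RPKM values (reads normalised for gene length and library size), which the authors averaged over each group of libraries, per the file headers, in 4 columns: xylan and glucose, exponential and stationary phase. The glucose libraries belong to another series and entered only through these means. The second table holds the authors' deposited log2 fold change for exponential phase, with no p-value, standard error or replicate; its direction was read from the values, which correlate with the ratio of xylan over glucose means (Pearson r = 0.84 across 3771 genes). The authors' normalization behind the log2 fold changes is not given in the sources used here. Of its 3812 entries, 27 hold no number and 1 an overflow value, which leaves 3784.

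Since the tables hold means, no replicate variance, test or p-value could be computed, and the planned count of calls by p-value was replaced by a limit of 1 on the absolute log2 fold change in the authors' deposited table. The planned Fisher's exact test over gene lists was not run, because genes of a single set of means are not replicates. Depth per sample is unknown, so no counting interval is given. The samples were grouped by the carbon source and growth phase in their labels. The labels carry no numbers that pair cultures across phases.

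For the ratios of means a pseudocount of 1 RPKM was added before log2, so folds of low genes are understated, and genes with a mean under 10 RPKM over the 4 columns were left out, which kept 3771. Changes are given relative to the median log2 ratio of these genes, together with counts as deposited. The phase change on xylan minus the phase change on glucose was taken per gene. Where the low end of a column is raised, as in both xylan columns, ratios of low genes between these columns lie nearer to 0, and their ratios to glucose lie higher.

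Gene names are those of the tables. Of 3812 names, 2357 were matched to the NCBI RefSeq gene table of assembly ASM1922v1 by locus tag and 561 by symbol, and 894 were not matched. The 4 gene names in the tables that carry positions had starts that were all found in that assembly after adding 1, so its coordinates are given, counted from 1. Gene lists were fixed as 24 patterns of gene symbols; 2 of them, for TonB-dependent receptors and sugar transporters of the major facilitator superfamily, had no member, because the names carry no product descriptions, and were not used. The 2 lists of transfer RNA and ribosomal RNA genes were added after the data were seen. A list's median was placed among the medians of 10000 random lists of the same size, as a description of these libraries. The random lists were drawn from 10 bins of mean RPKM over all 4 columns. A list high in 1 column was therefore matched to genes of higher level than its own in the other columns. Lists under 3 genes have no percentile. Phase changes were also simulated over 3771 genes, each drawn independently. Lists of 20 shifted by 1 on the log2 scale lay above 97.5% of random lists in 87 of 100 runs, lists shifted by 0.5 in 39 and unshifted lists in 1. Lists whose members move together, as neighbouring genes can, were not simulated, so these rates need not hold for them.

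The genes named were chosen by a rule set before the data were examined: for each comparison the 10 largest rises and 10 largest falls, all members of the 3 xylan and xylose lists, and the 2 members of every other list with the largest absolute change; genes without a product name could be counted without being named. Genes named outside the rule were chosen after their values were seen. Besides those of the closing section, they are ssrA, rpoS and CJA_0185. For the phase change on xylan they also are ntrC, nirB, nirD, glnD, CJA_3536, phoH and CJA_2157. The 5S copies rrfA, rrfB and rrfC and the 16S copies rrsA, rrsB and rrsC were added for the same change. For the stationary comparison with glucose they are glnD, glnE, gltB and gltD. Alternatives covered the pseudocount, the filter, centring, rescaling, the limit, the lists and the denominators, with quantile normalisation, subtraction of the 5th percentile of each column and file names alone added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.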

Results

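Transcript levels were measured by RNA sequencing in wild-type Cellvibrio japonicus, a soil bacterium that degrades plant cell wall polysaccharides, grown in MOPS defined medium with xylan as the carbon source. Cells were taken in exponential phase (3 cultures) and in stationary phase (3 cultures), biological triplicates according to the series design. The values analysed here are the authors' mean RPKM of each group for 3812 genes, the corresponding means of glucose-grown cells from another series, and the authors' deposited table of log2 fold changes of xylan over glucose in exponential phase. No value of a single culture was analysed here, so no spread between replicates, test or p-value can be given, and the depth of the libraries is unknown. A gene is called higher or lower below when its log2 difference is at least 1 in that direction, which is a rule of size and not a test.

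The 4 columns of means differed in shape. The 5th percentile of all genes was 49.4 RPKM in exponential and 47.1 RPKM in stationary phase on xylan, and 21.2 and 19.3 RPKM in the same phases on glucose. The 95th percentile was 549 and 469 RPKM on xylan against 928 and 989 RPKM on glucose. The transfer-messenger RNA gene ssrA (CJA_3895, chromosome positions 1443870 to 1444223), whose RNA rescues stalled ribosomes, took 29.4% of the summed RPKM in exponential and 21.4% in stationary phase on xylan, and 6.68% and 10.8% on glucose. Values near 50 RPKM in the xylan columns therefore lie at the low end of those columns.

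**Figure D1:**
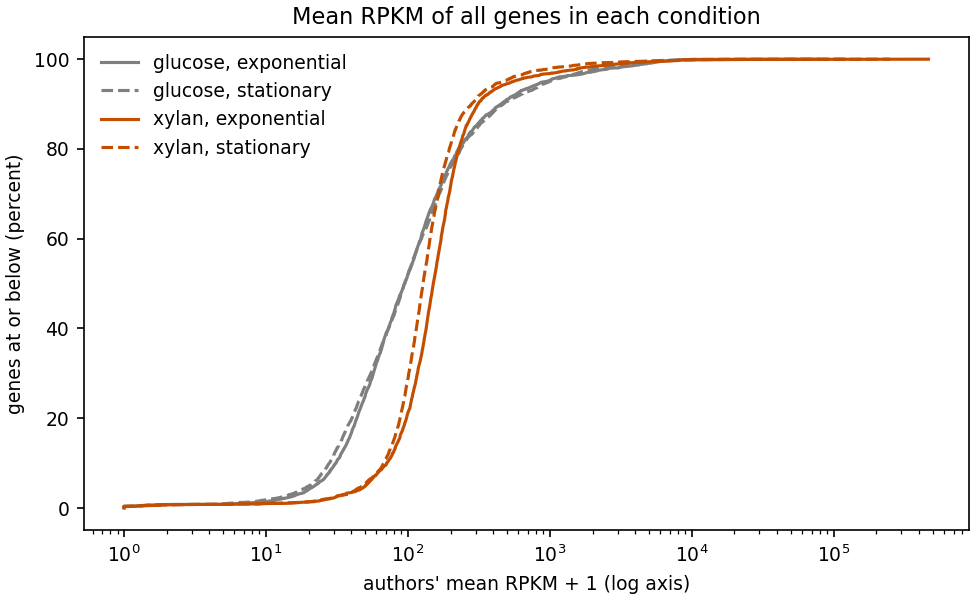
Cumulative percent of the 3812 genes (vertical axis) at or below each mean RPKM plus 1 (horizontal log axis) in the 4 conditions, with glucose in grey, xylan in orange, exponential phase solid and stationary phase dashed. The xylan curves start higher and are steeper, with 5th percentiles of 49.4 and 47.1 RPKM against 21.2 and 19.3 RPKM on glucose.

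The first comparison asked which genes differ between xylan and glucose during exponential growth. In the authors' deposited table, xylA, which encodes xylose isomerase, was higher on xylan by 4.30 on the log2 scale, with mean RPKM of 55.3 on glucose and 1225 on xylan. CJA_3062, which lies directly after xylA on the chromosome (positions 3634666 to 3636147) and has no symbol, was higher by 4.95 in the authors' deposited table. Of the 7 enzymes that cut the xylan backbone, 3 were higher and 0 lower, with a list median of 0.82 in the authors' deposited table. These were the endoxylanase genes xyn11B (2.65), xyn10C (2.26) and xyn11A (1.87) in the authors' deposited table, while xyn10D, xyn5A, xyn10B and xyn10A lay at 0.82, 0.72, 0.43 and 0.38. On xylan, xyn11B and xyn10C had a mean of 265 RPKM each, above the 75th percentile of all genes in that column (209 RPKM). The mean of xyn11A was 191 RPKM, above the column's median (150 RPKM). On glucose the means of xyn11B, xyn10C and xyn11A were 32.2, 41.3 and 30.7 RPKM, below the 25th percentile there (49.1 RPKM).

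Among the 22 enzymes that act on xylan side chains and xylo-oligosaccharides, 5 were higher, 0 lower and 17 between the limits in the authors' deposited table, with a median of 0.56. The higher members were gly43F (3.28), gla67A, an alpha-glucuronidase (2.06), gly43J (1.53), abf51A, an arabinofuranosidase (1.13), and axe2C, an acetyl xylan esterase (1.05), all from the authors' deposited table. The other 17 ran from -0.34 for ce2C to 0.93 for gly43B in the authors' deposited table. Among 10000 random lists of the same size matched on mean RPKM, the backbone list stood at percentile 99.65 and the side chain list at percentile 99.6. The gene xylE, the other member of the xylose list, had 0.61 in the authors' deposited table.

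**Figure D2:**
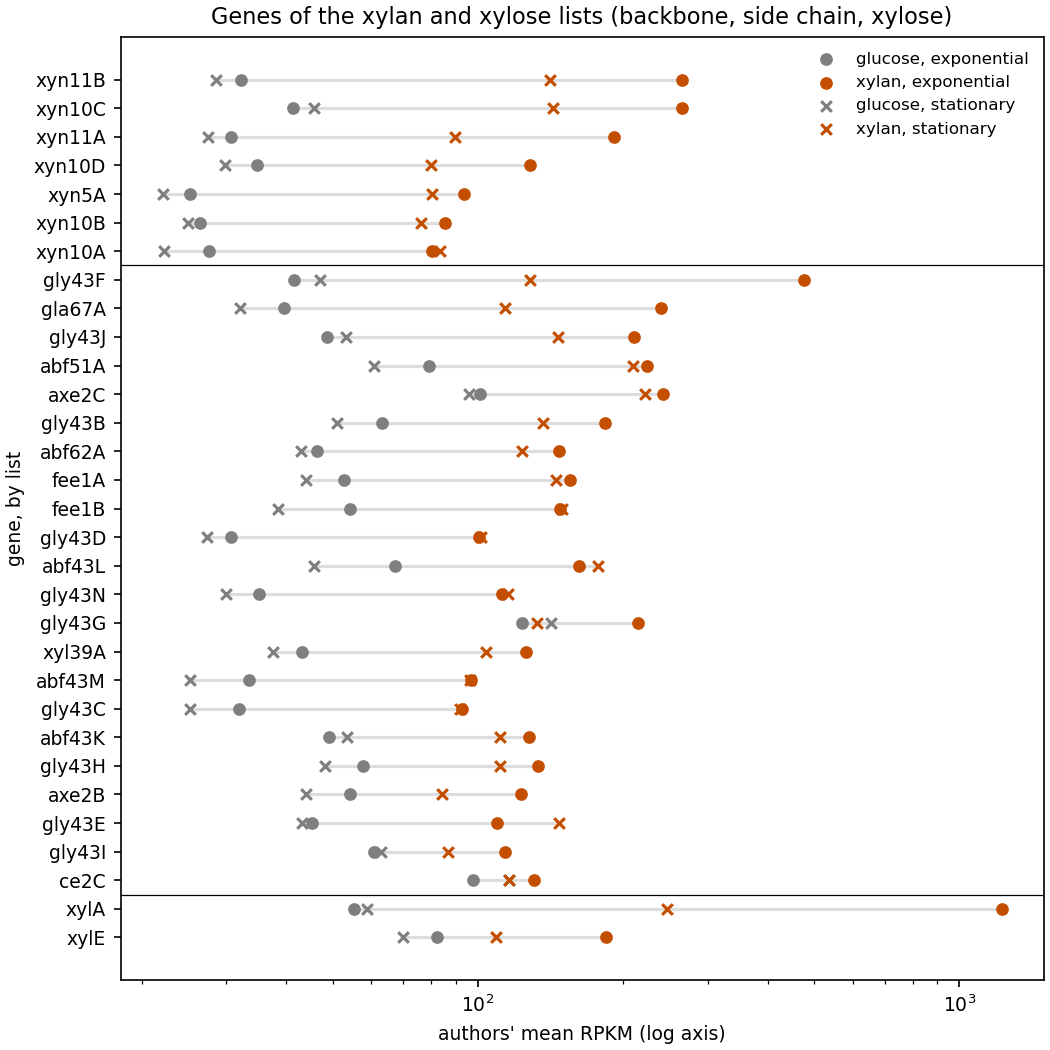
Mean RPKM (horizontal log axis) of each gene of the xylan backbone, side chain and xylose lists, separated by black lines and ordered within a list by the authors' log2 fold change, with glucose in grey, xylan in orange, circles for exponential and crosses for stationary phase; grey lines join the lowest glucose to the highest xylan value. The gene xylA reached 1225 RPKM on xylan in exponential phase, gly43F 475 RPKM, xyn11B 265 RPKM and xyn10C 265 RPKM.

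In the authors' deposited table the cellulose list had 4 of 24 members higher and 0 lower (median 0.53, percentile 99.64), with cbp2A at 1.29 and cbp2B at 1.18. The pectin and arabinan list had 4 of 19 higher (median 0.49, percentile 98.1), with rgl11A at 1.53 and pel1B at 1.21, and the chitin list 2 of 10 (median 0.57, percentile 97.47), with hex20B at 1.15 and chi18C at 1.08, in the authors' deposited table. The mannan list (median 0.36) had 1 of 10 members higher and 1 lower, man5E at -1.09, the starch list (0.23) 2 of 18 higher and 2 lower, with amy13B at -1.36, and the xyloglucan list (0.34) 0 of 6 past the limit, and all 3 lay between percentiles 79.28 and 84.05 in the authors' deposited table. The type II secretion genes, which export enzymes across the outer membrane, had a median of 0.58 (percentile 99.27) in the authors' deposited table. Of the 15 members 3 were higher and 12 lay between the limits. The higher ones included epsE (1.31) and epsG (1.27) in the authors' deposited table, whose symbols differ from the gsp symbols of the other members. The nitrogen assimilation list had 2 of 11 members higher and 1 lower in the authors' deposited table (median 0.69, percentile 99.21). Its largest values there were nirB at 1.02 and glnA at -2.04.

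Of the 14 tricarboxylic acid cycle genes, 10 were lower and 0 higher in the authors' deposited table (median -1.45, percentile 0.03), among them mdh (-2.36) and acnB (-2.12). The ATP synthase and NADH dehydrogenase list had 7 of 14 lower (median -1.0, percentile 4.10), with nqrC at -2.39 and nqrD at -2.17, and the ribosomal proteins 23 of 53 lower and 3 higher (median -0.71, percentile 3.94), with rplP at -2.04, in the authors' deposited table. The glycolysis list had 4 of 12 members lower, 1 higher and 7 between the limits (median -0.24, percentile 47.6) in the authors' deposited table. There gap was at -1.92 and CJA_2671, annotated tpiA, at 2.59, while CJA_0185, also annotated tpiA, was at 0.66 in the authors' deposited table. The pentose phosphate list had 1 of 7 lower, zwf at -1.15, and 0 higher (median 0.09, percentile 73.64) in the authors' deposited table. The flagella and chemotaxis list had 7 of 37 lower and 0 higher (median -0.51, percentile 0.28), with flgB at -1.86, and the transfer RNA synthetases 4 of 21 lower (median -0.64, percentile 0.48), with gltX at -1.23, in the authors' deposited table. The lowest values were those of CJA_1069 (-4.33), CJA_0697 (-3.48), fpr (-3.06), CJA_0472 (-2.71), etfA (-2.67), CJA_2519 (-2.64) and metE (-2.58) in the authors' deposited table. CJA_0697 is annotated tuf and has a near-identical copy, so its value is uncertain.

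Small structural RNAs led the other direction. The 5S ribosomal RNA copies rrfB, rrfA and rrfC were higher by 6.59, 6.31 and 5.99 in the authors' deposited table, with 3721, 3638 and 3651 RPKM on xylan against 12.9, 13.9 and 16.5 on glucose. Of 43 transfer RNA genes, a list added after the data were seen, 31 were higher and 1 lower in the authors' deposited table, with a median of 2.37. Copies of these RNAs can share reads, so values of single copies are uncertain. Since ribosomal RNA removal is not given, a change in the cells and a difference in library preparation cannot be told apart for them.

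By the limit of 1, 320 genes were higher and 434 lower in the authors' deposited table, among 3784 with a usable fold change. The ratio of the authors' means gave another picture for the same comparison, with a median shift of 0.64 over 3771 genes, 1332 genes higher and 289 lower as deposited, 398 and 660 relative to that shift, 670 and 514 with each column rescaled to the same total, and 256 and 365 with the columns quantile normalised. From the means relative to the shift, the backbone list (median 1.22, percentile 99.9) and the side chain list (0.86, percentile 99.95) stayed above 0. The mannan (0.60), starch (0.68) and xyloglucan (0.65) lists were above 0 too, at percentiles 82.31, 85.01 and 85.53, so a median above 0 alone does not set a list apart. The tricarboxylic acid cycle list (-2.51, percentile 0.01) stayed below 0, while the type II secretion list was at -0.15 against 0.58 in the authors' deposited table. The flagella and chemotaxis list (median -0.56, 11 of 37 lower and 0 higher) lay at percentile 53.75 from the means, in the middle of matched random lists, against 0.28 in the authors' deposited table, and the type II secretion list at 88.71 against 99.27. The ribosomal list (percentile 0.48), the ATP synthase and NADH dehydrogenase list (0.20), the stress list (2.23) and the chitin list (99.43) lay outside the middle 95% from the means and inside it in the authors' deposited table. More members were lower from the means in the glycolysis list (8 of 12, with 2 higher, median -1.45, percentile 15.4) and the pentose phosphate list (4 of 7, median -1.06, percentile 27.4). The same held for the transfer RNA synthetases (17 of 21, median -1.29, percentile 0). Carbon source and series cannot be separated, because the glucose libraries belong to another series.

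In stationary phase, xylan against glucose, ratios of means are given relative to the median shift of 0.54. The nitrogen assimilation list had 7 of 11 members higher on xylan (median 2.04, percentile 100), led by CJA_0528, annotated ntrB (5.78), and ntrC, a nitrogen response regulator (4.18), while glnD was lower (-1.92) and glnE (-0.11), gltB (-0.68) and gltD (-0.58) lay between the limits. With lists from file names alone, an alternative chosen after the data were seen that leaves out CJA_0528, the nitrogen median was lower. Outside the nitrogen list, xdhA, a subunit of xanthine dehydrogenase (6.40), and CJA_0956, annotated as the urea transport gene urtA (6.28), were among the 10 largest values. CJA_3392, CJA_0775 and CJA_0565 had the largest values (8.14, 7.87 and 7.19), with 14552, 17721 and 7201 RPKM on xylan and 34.6, 51.3 and 32.9 RPKM on glucose. All 53 ribosomal protein genes were lower on xylan (median -4.99, percentile 0), with rpmC at -6.28 and rpsQ at -6.10, and so were all 14 ATP synthase and NADH dehydrogenase genes (median -4.27). CJA_1304, CJA_1305 and CJA_1306 were at -6.23, -6.49 and -5.83, with 7524, 4585 and 5007 RPKM on glucose and 145, 73.4 and 127 RPKM on xylan.

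At this phase the backbone list had a median of 1.12 with 6 of 7 higher, inside the middle 95% of matched random lists (percentile 95.67), and the side chain list a median of 0.94 (percentile 99.24) with 10 of 22 higher, 0 lower and 12 between the limits, among them ce2C (-0.54), gly43G (-0.63) and gly43I (-0.09). The largest values were 1.73 for xyn11B, 1.40 for fee1B and 1.40 for abf43L, and xylA was at 1.52. All backbone genes lay between 76.0 and 143 RPKM on xylan and between 22.1 and 45.7 RPKM on glucose. On xylan, xyn10C (143 RPKM) and xyn11B (141 RPKM) lay above the median of all genes in that column (127 RPKM) and the other backbone genes below its 25th percentile (94.1 RPKM). The pectin and arabinan list was at 1.15 with 14 of 19 members higher, and the chitin list at 1.11 with 6 of 10.

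Over all genes, 1348 were higher and 621 lower as deposited, 722 and 947 relative to the shift, and 614 and 709 with the columns quantile normalised. The split thus depends on the scaling, and the glucose libraries belong to another series here too.

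The comparison within this series was stationary against exponential phase on xylan, which asked what changes as growth stops. Values are given relative to the median shift of -0.19. Ribosomal protein genes were lower in stationary phase in 52 of 53 cases (median -3.74, percentile 0), with a median level of 1644 RPKM in exponential and 111 RPKM in stationary phase. Among them rpsJ was at -5.87 and rplL at -5.60. The list took 7.80% of the summed RPKM in exponential and 0.66% in stationary phase, or 13.4% and 0.941% with the 10 genes of highest mean left out of the sum. The ATP synthase and NADH dehydrogenase genes were lower in 14 of 14 cases (median -1.88, percentile 11.04), with atpG at -2.79, and the tricarboxylic acid cycle genes in 7 of 14 (median -0.86, percentile 51.94), with sdhA at -1.83. The transfer RNA synthetases were lower in 6 of 21 cases (median -0.76, percentile 0.01), with thrS at -1.47. Many of these stationary values, such as 111 RPKM for the ribosomal median, lay between the 25th percentile of all genes in that column (94.1 RPKM) and its median (127 RPKM).

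The flagella and chemotaxis list had 32 of 37 members higher and 0 lower in stationary phase (median 1.89, percentile 100), with flgB and flgG both at 3.03, and its median level went from 140 to 457 RPKM. In the nitrogen assimilation list 6 of 11 members were higher and 1 lower (median 2.16, percentile 99.99). These were glnA, glutamine synthetase (4.39; 319 to 5907 RPKM), CJA_0528 (4.38), ntrC (4.04), CJA_3536, annotated glnL (3.17), and the nitrite reductase genes nirB (2.17) and nirD (2.16), and the lower member was glnD (-1.02). Removing the member with the largest change took the list's median, as deposited, from 1.97 to 1.11, and lists from file names alone, an alternative chosen after the data were seen, took it to 0.93. The type IV pili list had 5 of 22 higher and 1 lower (median 0.51, percentile 99.83), with pilG at 2.07 and pilH at 2.02, and the stress list 5 of 17 higher and 2 lower (median 0.34, percentile 98.46), with rpoS, the stationary phase sigma factor, at 1.54, and the chaperonin genes groES at -2.19 and groL at -1.75. The phosphate uptake list had 0 of 8 past the limit (median 0.23, percentile 81.02).

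Xylan genes had lower or similar levels in stationary phase. The gene xylA was at -2.12, going from 1225 to 247 RPKM, and gly43F at -1.70, going from 475 to 128 RPKM. The backbone list had a median of -0.49 (percentile 0.60) with 0 of 7 past the limit, led by xyn11A at -0.90, and the side chain list a median of 0.00 (percentile 30.99) with 1 of 22 lower. The cellulose list had 1 of 24 members higher, cel5H at 1.11.

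The highest values were those of CJA_3392 (7.0), CJA_0775 (6.96), CJA_1425 (6.57), CJA_1426 (6.56) and CJA_0565 (6.00), none with a symbol. The 23S ribosomal RNA copies rrlA, rrlB and rrlC were at 5.57, 5.55 and 5.55 and the 16S copies rrsA, rrsB and rrsC at 5.22, 5.23 and 5.22, while the 5S copies rrfA, rrfB and rrfC were at -4.85, -4.93 and -4.97; copies share reads. All 9 ribosomal RNA genes together took 0.781% of the summed RPKM in exponential and 4.28% in stationary phase. Ribosomal RNA removal is not given in the sources used here. For ribosomal and transfer RNA, a change in the cells and a difference in library preparation therefore cannot be told apart. At least 6 of the 10 lowest values belonged to annotated transfer RNA genes, with CJA_3889 at -7.22, and 36 of 43 transfer RNA genes were lower (median -3.08). CJA_2671, annotated tpiA, was at -5.28, going from 3966 to 88.6 RPKM, while CJA_0185, also annotated tpiA, was at -0.26. Over all genes 320 were higher and 488 lower as deposited, 394 and 385 relative to the shift, 555 and 560 with the columns quantile normalised, and 555 and 285 with each column rescaled to the same total.

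**Figure D3:**
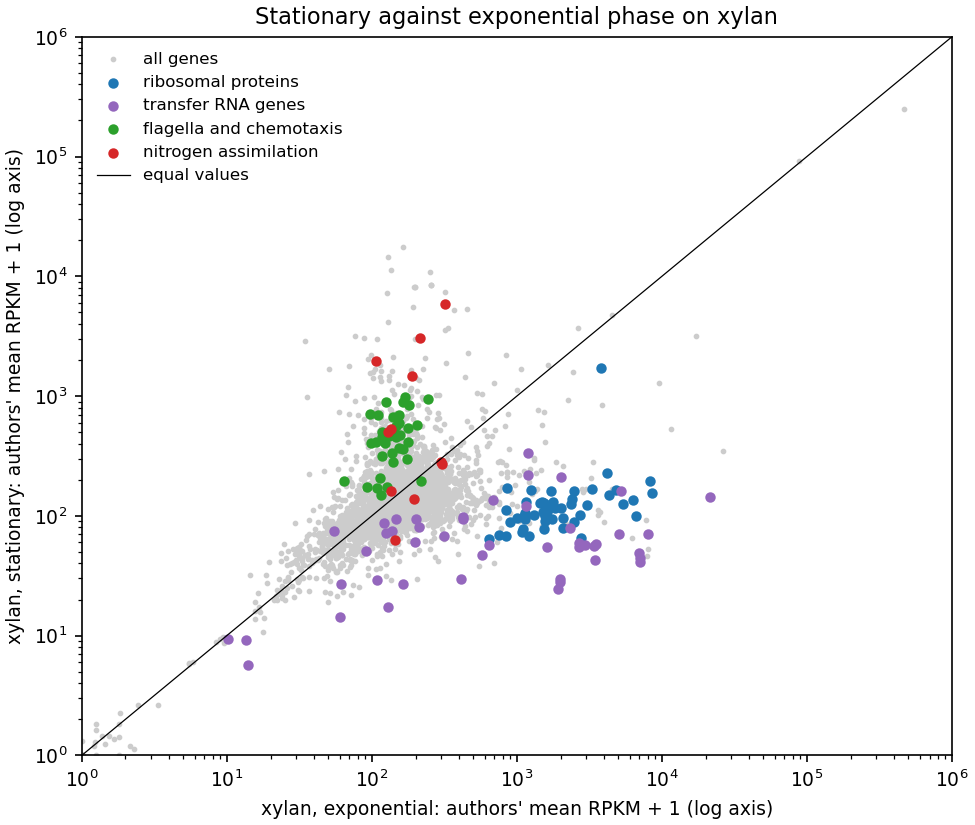
Mean RPKM plus 1 of every gene in exponential (horizontal log axis) and stationary phase (vertical log axis) on xylan; colours mark 4 gene lists, grey points all genes and the line equal values. Ribosomal protein genes lie at a median of 1644 RPKM in exponential and 111 RPKM in stationary phase, and flagella and chemotaxis genes at 140 and 457 RPKM.

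The last comparison set the phase change on xylan against the phase change on glucose, relative to a median difference of -0.14. Both glucose columns belong to another series, so differences between the carbon sources cannot be separated from differences between the series here either. Ribosomal protein genes were lower in stationary phase in 52 of 53 cases on xylan (median -3.74) and in 9 of 53 on glucose (median -0.83), where the other 44 lay between the limits, and all 53 differed by at least 1 between the carbon sources (median difference -2.83). Flagella and chemotaxis genes had 1.89 on xylan and 0.46 on glucose, with 28 of 37 past the limit for the difference (median 1.44). Nitrogen assimilation genes had 2.16 on xylan and -0.07 on glucose, with 6 of 11 past the limit (median 1.95), among them CJA_0528 (4.72) and glnA (4.42). The type II secretion list had a median difference of -0.77 (percentile 0.02), with 2 of 15 members higher, epsE (2.62) and epsG (2.30), 2 lower and 11 between the limits. The gene xylA differed by -2.25 and gly43F by -1.92.

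Some genes changed with phase mainly in the glucose columns, which belong to another series. CJA_1305, CJA_1304 and CJA_1306 were higher in stationary phase on glucose by 6.90, 6.70 and 6.48 and differed between carbon sources by -6.71, -6.20 and -6.25, and CJA_3465, annotated zigA, was higher on glucose by 5.81. CJA_2157, annotated rmf, which makes ribosomes dormant, was higher on glucose by 2.91 and on xylan by 4.74, and phoH by 2.36 and 5.04. Across 3771 genes the phase changes had a Pearson r of 0.40 and a Spearman rho of 0.42, where genes are not independent replicates. Of the 779 genes past the limit on xylan, 78.2% had the same sign on glucose. The standard deviation across genes was 1.23 on xylan and 0.52 on glucose. For the difference, 277 genes were higher and 484 lower as deposited, 487 and 528 with the columns quantile normalised, and 498 and 285 with each column rescaled to the same total.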

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

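The quantile normalised columns, the subtraction of each column's 5th percentile and lists from file names alone were chosen after seeing the data. Reversals were counted only for list medians and named genes' ratios of means of at least 1 in size. None of those reversed direction under any alternative run. Smaller values could change sign. With centring, the type II secretion median for xylan against glucose in exponential phase went from 0.48 to -0.15. The authors' fold changes of single named genes were put under no alternative. Pseudocounts of 0.1 or 5, no filter and a minimum mean of 50 RPKM kept all counts within 1.5 times. Over all alternatives 32 of 78 counts moved further, while 638 of 700 list medians, 1914 of 2124 named gene values and 154 of 176 shares moved by less than 1.5-fold. Of these medians, 100 could not move, because symbol patterns alone gave the main lists. Centring and rescaling shift a whole comparison by about 1 constant. Centring therefore moved 20 of 80 medians by more than 1.5-fold, and the other 60 could not move that far. Neither could the 354 named gene values under centring or the 354 under rescaling. With the 5th percentile subtracted 121 of 354 named gene values moved further, and with quantile normalisation 89 of 354. Within a column every share moved by the same factor. With 5 expression bins 1 of 40 list percentiles moved. The 22 shares that moved further were all in the exponential xylan column with the 10 genes of highest mean left out of the sum, where the ribosomal share was 13.4% in place of 7.80%. A limit of 2 gave 56 higher and 37 lower genes in the authors' deposited table, and no limit gave 1950 and 1833. A limit of 2 on ratios of means gave 131 higher and 56 lower for xylan against glucose in exponential phase, 288 and 271 in stationary phase, 127 and 185 for the phase change on xylan, and 108 and 166 for its difference from glucose; a stricter limit can only lower counts. Centring on the median gave 398 and 660 in exponential and 722 and 947 in stationary phase. Rescaling to the same total gave 670 and 514 in exponential phase, 555 and 285 for the phase change on xylan, and 498 and 285 for the difference. Quantile normalisation gave 256 higher genes in exponential and 614 in stationary phase, 555 for the phase change and 487 for the difference. Subtracting the 5th percentile gave 613 lower genes in exponential and 1015 in stationary phase, 590 higher and 872 lower for the phase change, and 561 and 860 for the difference. For the phase change on xylan, the ribosomal median was -4.76 after that subtraction, the flagella median 2.74 after quantile normalisation, and the nitrogen median 3.11 after quantile normalisation, 1.11 without its most changed member and 0.93 with file names alone. Apart from limits and left-out members, the cause was not tested. Alternatives on p-values, product patterns and single replicates were not run, because the tables hold none of these. Depth is unknown, so how far it limits low genes cannot be stated.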

Other observations

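All tests in this part were chosen after the values were seen, as were the genes named here outside the fixed rule. Beyond the nitrogen list, a run of neighbouring genes for purine breakdown was higher in stationary phase on xylan, relative to all genes: xdhA (4.01), xdhB (3.24), CJA_0548, annotated xdhC (3.21), CJA_0549, annotated uraD (2.81), CJA_0550, annotated uraH (3.28), and CJA_0551, annotated guaD (2.84). On glucose the same genes lay between -0.61 and 0.16. A pair of urea transport genes annotated urtA, CJA_0956 and CJA_1241, were at 4.66 and 4.63 on xylan, the formamidase gene fmdA at 4.11, and CJA_1243 and CJA_1244, annotated uca and atzF for urea carboxylation and allophanate hydrolysis, at 1.75 and 2.20. The genes CJA_0566 to CJA_0571, which have no symbol, were at 3.56 to 5.56 on xylan and at -0.40 to -0.02 on glucose. The protease genes clpA and clpS were at 3.35 and 2.23 on xylan and 0.999 and 0.28 on glucose.

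In stationary phase on xylan 6 of 11 nitrogen assimilation genes were higher and 1 lower. Against glucose the list stood apart already in exponential phase (median 0.69, percentile 99.21 in the authors' deposited table, 99.4 from the means). There glnA was lower on xylan, at -2.04 in the authors' deposited table, with 1949 RPKM on glucose and 319 RPKM on xylan. A single scale factor between the xylan columns would leave the nitrogen list among matched random lists, and it lay at percentile 99.99. An even background would add the same RPKM to every gene, at most about the 5th percentile of the stationary column (47.1 RPKM), and the median gain of the 11 members was 374 RPKM, with 6 of them above that level. A hypothesis is that the stationary xylan cultures were short of nitrogen; the phosphate list, at percentile 81.02, lay among random lists, but in lists looked at after that value the flagella (100), type IV pili (99.83) and stress (98.46) genes stood apart too, and phoH, named for phosphate starvation, was at 5.04, so the contrast with phosphate does not decide. On glucose those 3 lists also stood apart (percentiles 100, 99.96 and 97.84) and the nitrogen list did not (42.2), but no measurement of the medium was analysed here, and the nitrogen median as deposited is 1.11 without its most changed member and 0.93 with file names alone, so a shortage of nitrogen and another response to stationary phase on xylan cannot be told apart.

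The authors' fold changes differed from the ratio of their own means by a median of 0.69 on the log2 scale. A single scale factor is argued against, since the median absolute difference was 0.397 after the median difference was removed. After quantile normalising the exponential columns to each other it was 0.042, with a Pearson r of 0.996 across genes, so quantile normalisation before the fold change is a candidate explanation. The difference concerns 2 sets of values from the same libraries, and no biological explanation was tested.

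The low end of the xylan columns was raised. A single scale factor is argued against, because the ratio of the 95th to the 5th percentile was 3.94 times larger for glucose than for xylan in exponential phase. An even background such as genomic DNA could give a decline of low genes with distance from dnaA in growing cells. The Spearman rho on xylan was -0.249 in exponential phase, where glucose gave -0.0064. The xylan value lay inside the middle 95% of rotations along the chromosome (-0.252 to 0.251) and outside that of shuffled blocks of 50 genes (-0.136 to 0.144). In stationary phase rho was -0.103 on xylan, also inside the rotations (-0.104 to 0.114) and outside the blocks (-0.093 to 0.098), and 0.073 on glucose. On simulated columns of 2922 genes the rotations found 10 of 20 declines and called 2 of 20 columns with none, and the shuffled blocks, added for that reason, found 20 and called 0 of 20, but the check itself used fewer genes and is void, because 1370 of the 1886 low genes (72.6%, under the 80% needed) had a position. A background, a true rise of low genes on xylan and a difference between the series therefore cannot be told apart.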
